A study of Homo sapiens with 16 samples.

How the data were processed

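Chromatin immunoprecipitation sequencing (ChIP-seq) with an antibody to AIB1, the nuclear receptor coactivator encoded by NCOA3, was applied to MCF10A cells, a non-tumorigenic human mammary epithelial line, to MCFDCIS cells, a derivative line that models ductal carcinoma in situ, and to the D4 counterpart of each. Per the labels' protocols, chromatin was crosslinked with 1.2% formaldehyde, sonicated and immunoprecipitated with a low-cell-number kit, and the medium held EGF, hydrocortisone, cholera toxin, insulin and horse serum. The labels list 16 samples, which are 3 ChIP samples and 1 input sample for each of 4 groups. Nothing in the labels says whether the 3 samples of a group came from separate cultures.

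The authors deposited 4 lists of genomic regions, called clusters here, with 1 list per group and no value per replicate. Per the series' design text the ChIP samples were normalized to cell lysate input, and per the submitters' processing notes the build was hg19 (GRCh37). The aligner, the caller, the threshold and the number of regions tested are not given in the sources used here. Each cluster has a position and the authors' deposited score, a number whose definition the files do not state. It was used to rank or filter clusters within a list, and for 1 added alternative in which parental clusters were held to a limit taken from a D4 list, which assumes that the score has the same scale in both. The planned test of scores between lists was not made. The lowest score was between 7.00 and 7.11 in every list, as a shared cutoff would give. Sequencing depth is unknown, so intervals on shares cover the number of clusters only, and all tests compare lists of regions, not replicate cells. Clusters shared between lists count in each of them, so the sets compared between lists are not independent.

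The file names and the sample descriptions cross the cell lines. The descriptions of the MCFDCIS samples cite the lists named after MCF10A and the reverse, whereas parental and D4 status match. The lists are therefore called MCF10A-named and MCFDCIS-named, and no list was assigned to a cell line. Taking the line from the descriptions exchanges the names and leaves each value as it is.

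Clusters were compared with the GRCh37 sequence and GENCODE release 44 lifted to that build, with 20090 protein-coding genes. All 1378 clusters lay within the chromosome ends of that build. Clusters were placed at random 10000 times on their own chromosome, outside assembly gaps, with their widths kept, and p-values from placements are one-sided with 0.0001 as the smallest they can give. For GC content 1000 placements were used, with 0.001 as the smallest p. Overlap meant at least 1 bp, and a promoter was the stretch within 1 kb of a protein-coding transcription start site (TSS). For 13 fixed gene lists, members with a cluster within 100 kb of the TSS were counted against the placements, with Benjamini-Hochberg adjustment over 52 tests. For 12 consensus motifs, the central 500 bp of each cluster was compared with windows of the same width 5 kb to either side by Fisher's exact test, two-sided, adjusted over 48 tests, and parental with D4 lists over 24 tests. Medians were compared by permutation tests with 100000 resamples, two-sided. Differences of D4 minus parental shares were compared between line names by permutation in 14 tests. Intervals of shares are exact (Clopper-Pearson) 95% intervals, and those of differences use the normal approximation. Second matches of a cluster's central 100 bp were sought with minimap2 2.31 at an identity of at least 95% over at least 90 bp. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9 were used.

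The named clusters followed a rule fixed before the data were examined: the 5 with the highest score in each list, those in all 4 lists, those within 100 kb of NCOA3, and, for each gene list past its threshold in any cluster list, up to 8 members with a cluster within 100 kb. Tests, gene lists and the first set of other settings were also fixed then. Chosen after seeing the data were the restriction of tests to the 20 chromosomes that hold clusters, the dense regions (adjoining 1 Mb bins with at least 20 clusters over the 4 lists), the limit of 500 bp, the filter on second matches, the chance drawn from the union of the lists, the split into shared and unshared clusters within a line name and by both parental lists, the filter by the D4 score, the set without promoter clusters, the comparison of stronger with weaker clusters within a list and the test of the dense-region share between line names. Members of gene lists on chromosomes 20, 21 and 22 were left out. The repeat share could not be computed because the reference sequence had no lower-case bases.

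The methods were tested on simulated clusters. Of 40 random lists set against the MCFDCIS-named parental list 0 passed 0.05 in the overlap test, and 60 of 60 planted overlaps were found. A planted AP-1 share of 30% was recovered as 30%, and 10 of 10 planted glucocorticoid targets were found, with 0 of 52 gene list tests past 0.05 on random lists. The planted overlaps, motifs and targets met the counting rules by construction. Their recovery therefore checks the counting only, not the power of the tests. The random lists were drawn by the same placement rule as the tests, so few passes were expected from the design. They do not show how often the tests pass for lists chosen from a common set of regions or for crowded clusters. With equal shares, 11 of 200 sets passed 0.05 in the test between line names, and with clusters spread by chromosome length 6 of 150 tests did.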

Results

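The series asked where AIB1 isoforms bind the genome in MCF10A and MCFDCIS mammary epithelial cells and in the D4 counterpart of each line. Each of the 4 groups had 3 ChIP samples and 1 input, and each was represented by a single list of clusters without replicate values, and how the samples of a group were combined is not given in the sources used here. No replicate error could therefore be given for any value. The cell line of a list is uncertain, because the sample descriptions cite the lists of the other line, so the lists are named by line name and by parental or D4 status, and a difference between line names has no known direction between the cell lines.

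Far fewer AIB1 clusters were listed for D4 cells than for parental cells under both line names. The MCF10A-named lists held 490 parental and 138 D4 clusters, a ratio of 3.55, covering 348.4 kb and 141.5 kb. The MCFDCIS-named lists held 651 parental and 99 D4 clusters, a ratio of 6.58, covering 413.1 kb and 70.8 kb. No test applies to counts from single lists, and differences in sequencing depth could not be assessed. No cluster lay on chromosomes 20, 21 or 22 in any list, although they hold 59.5, 35.1 and 34.9 Mb of sequence. Whether the authors' run or the deposited lists covered these chromosomes is not known, so the gap does not show that AIB1 binding is absent there. The NCOA3 gene, which encodes AIB1 and lies on chromosome 20, was therefore not analysed here.

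**Figure D1:**
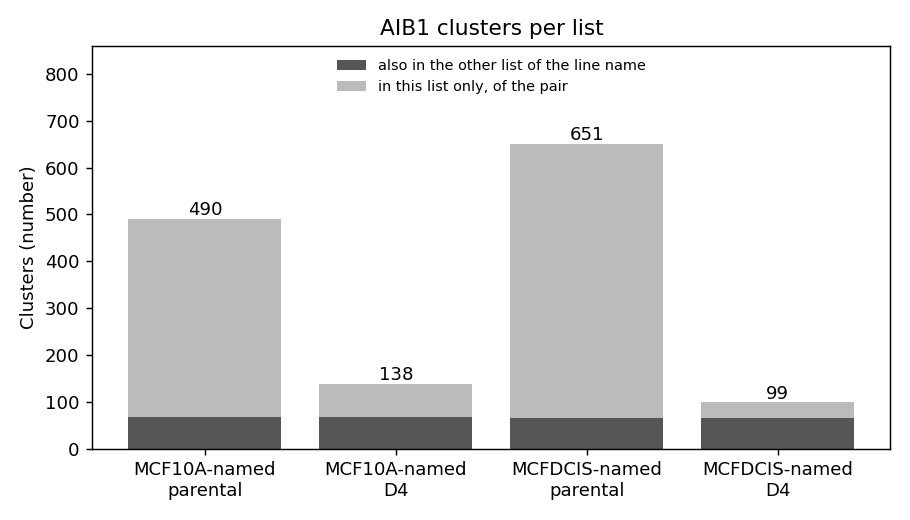
Number of AIB1 clusters in each of the 4 lists (bars), with the part shared with the other list of the same line name in dark grey. The D4 lists hold 138 and 99 clusters against 490 and 651 in the parental lists, and 67 and 65 are shared.

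Many of the D4 clusters were also parental clusters. In the MCF10A-named pair 67 of 138 D4 clusters, 48.6% (exact 95% interval 40 to 57.2), overlapped a parental cluster, and in the MCFDCIS-named pair 65 of 99 did, 65.7% (55.4 to 74.9). With clusters above the median score of both lists these shares were 21.7% (15 of 69) and 50% (25 of 50). The filter also removed the weaker parental clusters, which can lower these shares by itself. They therefore do not show that higher-scored D4 clusters are shared less. Crossed between the line names, 55 of 138 MCF10A-named D4 clusters (39.9%, 31.6 to 48.5) were in the MCFDCIS-named parental list and 39 of 99 MCFDCIS-named D4 clusters (39.4%, 29.7 to 49.7) in the MCF10A-named one. Outside the dense regions described below, 35 of 88 MCF10A-named D4 clusters were in the parental list of their own name and 45 of 88 in the other. The parental lists shared 307 clusters, 62.7% of the 490 and 47.2% of the 651, whereas the D4 lists shared 9, 6.52% and 9.09%. With clusters above the median score of both D4 lists 1 of 69 (1.45%) was shared, a value that the filter can also lower by itself. Random placement gave at most 4 overlaps in any pair, with p = 0.0001, the smallest possible, for each of the 12 directed comparisons (one-sided, the smallest list with n = 99). Overlapping clusters had identical ends in every pair, so the lists share a common set of regions whose size is not given in the sources used here. The 4 lists together held 897 different clusters, and independent draws from these 897 would share 75.4 and 71.8 clusters between D4 and parental lists, more than the 67 and 65 observed. This union holds listed regions only, which raises the expected number by construction, so it is a bound, and the excess over chance depends on how many regions beyond these were tested.

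Only 6 clusters were in all 4 lists. They included those at chromosome 1:222065151-222065360, 149.7 kb from the TSS of DUSP10, a phosphatase of stress-activated MAP kinases; at chromosome 2:67691051-67691260, 66.6 kb from ETAA1; at chromosome 5:148521401-148521410 in intron 1 of ABLIM3; at chromosome 16:21566651-21566660, 44.2 kb from METTL9; and at chromosome 17:17726301-17729360 in intron 1 of SREBF1, a regulator of lipid synthesis. The METTL9 cluster had 1 other close match in the genome, and the SREBF1 cluster lay in a region dense in clusters.

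The highest scored parental clusters included a known glucocorticoid-responsive gene under both line names. In the MCFDCIS-named parental list the first was at chromosome 17:8057651-8057860, 1.93 kb from the TSS of PER1, a circadian clock gene induced by glucocorticoids, with 191.5 in the authors' deposited table. It was followed there by clusters in intron 3 of MCF2L2 (166.8), within SH3TC2 (162.5), in intron 2 of RAI1 (158.7) and 54.5 kb from CDKN2AIPNL (156.7). In the MCF10A-named parental list the authors' deposited table ranked intron 9 of PRKCH, a protein kinase C gene, first with 96.5, followed by the CDKN2AIPNL cluster (94.0), the DUSP10 cluster (89.0), the PER1 cluster (86.6) and a 6410 bp cluster 63.6 kb from MYC (80.4). The PER1 cluster was also in the MCFDCIS-named D4 list and not in the MCF10A-named D4 list.

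In the MCF10A-named D4 list the authors' deposited table ranked a 5510 bp cluster at chromosome 8:129137201-129142710 first (42.1), 388.7 kb from MYC, followed by clusters 40.3 kb from FGF1 (31.8), in intron 1 of SMG9 (22.8), at the promoter of CYP1B1 (19.7) and 205.8 kb from P3H2 (19.7). In the MCFDCIS-named D4 list the authors' deposited table placed first, with equal scores of 25.5, a cluster 7.92 kb from GOLGA6D, with 3 other close matches in the genome, and the promoter shared by RPP14 and HTD2. The promoter of PSMA3, a proteasome subunit gene, came next (23.5), then a cluster within ABLIM1 (21.9) and a cluster 79.8 kb from IRX4 (19.0). Scores were not tested between lists.

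Parental clusters lay near glucocorticoid targets, basal and myoepithelial genes and growth factor signalling genes more often than random placement allowed. Of 24 glucocorticoid targets, 9 had a cluster within 100 kb in each parental list, against 0.751 and 0.925 by placement (n = 24 genes, one-sided placement test, adjusted p = 0.0026 for both). Besides PER1 these included FKBP5, a steroid receptor chaperone, with a cluster at chromosome 6:35695901-35695960, 39.2 kb from its TSS, the metallothionein gene MT2A at 1.14 kb, whose cluster also counts for MT1X, the sodium channel gene SCNN1A at 0.772 kb and the transcription factor gene KLF9 at 5.43 kb, all in both parental lists. In the MCFDCIS-named D4 list 2 of 24 had a cluster, PER1 and FKBP5 (n = 24 genes, adjusted p = 0.0444), and in the MCF10A-named D4 list 0 of 24 did (adjusted p = 1). The FKBP5 cluster of that MCFDCIS-named D4 list was a different one, at chromosome 6:35569801-35569810, 86.9 kb from the TSS. The call in the MCFDCIS-named D4 list was lost with a 25 kb window (n = 24 genes, adjusted p = 0.182) and with clusters above the median score (0.237).

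Of 25 basal and myoepithelial genes, 8 had a cluster in each parental list (n = 25 genes, adjusted p = 0.00347 in the MCF10A-named and 0.0195 in the MCFDCIS-named list). KRT17, KRT6A, KRT5, KRT14 and KRT16, which encode basal and stress keratins, were among them, but the keratin genes near a cluster lie at only 2 loci, on chromosomes 12 and 17, and share their clusters, and keratin genes were not tested on their own. The KRT17 cluster, at chromosome 17:39780951-39781010, was 0.124 kb from the TSS and the KRT6A cluster, at chromosome 12:52888451-52888510, 1.41 kb. ERBB, IGF and insulin signalling genes counted 6 and 7 of 34 (n = 34 genes, adjusted p = 0.0253 for both), among them the EGFR ligand genes EREG at 9.49 kb and AREG at 70.3 kb, which share a single cluster at chromosome 4:75240351-75240510, EGFR at 51.4 kb, whose cluster also counts among the basal genes, and HRAS at 0.816 kb. Extracellular matrix and protease genes counted 5 and 6 of 26 (n = 26 genes, adjusted p = 0.0444 and 0.0364), including the integrin gene ITGB6 at 28.5 kb. With a 25 kb window the basal call in the MCF10A-named list and the signalling and matrix calls in both parental lists were lost (n = 25, 34 and 26 genes, adjusted p = 0.0896 for basal genes, 0.224 and 0.0896 for signalling and 1 and 0.711 for matrix genes). The matrix call in the MCFDCIS-named list was also lost with clusters above the median score (n = 26 genes, adjusted p = 0.179).

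YAP-TEAD targets, the genes of the Hippo pathway effectors, counted 5 of 30 in the MCF10A-named parental list (n = 30 genes, adjusted p = 0.0364) and 4 of 30 in the MCFDCIS-named one (adjusted p = 0.235), with AXL at 6.97 kb and AMOTL2 within 100 kb in both. The first of these calls was lost with a 25 kb window (n = 30 genes, adjusted p = 0.205). AP-1 and immediate early genes counted 6 of 26 in both (n = 26 genes, adjusted p = 0.0218 and 0.0507), including FOSL1 at 15.5 kb and FOS at 24.2 kb in both lists. EMT and mesenchymal genes counted 1 and 5 of 26 (n = 26 genes, adjusted p = 1 and 0.0516), luminal genes 2 and 3 of 24 (0.461 and 0.224), and NF-kB and inflammatory genes 2 of 25 in both (0.466 and 0.66). E2F and cell cycle genes and coactivators and corepressors had 0 members near a cluster in any list. Genes of cells not expected in these lines did not pass either, with 3 of 24 blood cell genes in both parental lists (0.224 and 0.331) and 0 and 2 of 22 neuronal genes (1 and 0.506). Placement gave 0.941 and 1.24 blood cell genes and 0.929 and 1.13 neuronal genes. In the MCF10A-named parental list the blood cell excess was, in proportion, not far below 3 of the calls. These were signalling (6 against 1.47), matrix (5 against 1.23) and YAP-TEAD genes (5 against 1.28). Placement took no account of gene density or GC content. In the D4 lists no gene list passed other than the glucocorticoid targets above, and none of 26 Fisher's exact tests of D4 against parental-only genes passed after adjustment.

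AP-1 sites, bound by FOS and JUN proteins, marked the clusters of all lists but the MCFDCIS-named D4 list. In the MCF10A-named lists 27.6% of parental clusters (exact 95% interval 23.6 to 31.7) held the consensus against 10.1% of flanking windows, and 21.0% of D4 clusters (14.5 to 28.8) against 6.88% (Fisher's exact test, adjusted p = 1.71e-15 and 0.000584). In the MCFDCIS-named lists 28.6% of parental clusters (25.1 to 32.2) held it against 9.14% (Fisher's exact test, adjusted p = 1.49e-25), but 11.1% of D4 clusters (5.68 to 19.0) against 12.1% (adjusted p = 1). The D4 share was 17.5 points lower there, a D4 minus parental difference of -17.5 points (-24.6 to -10.4, Fisher's exact test, adjusted p = 0.00296). The difference was -6.54 points (-14.4 to 1.33, adjusted p = 0.433) in the MCF10A-named pair, and the permutation test between line names gave p = 0.0541 (adjusted p = 0.252). The MCFDCIS-named difference was -5.61 points when whole clusters were searched (Fisher's exact test, adjusted p = 0.621) and -6.58 points against parental clusters no stronger than the D4 upper quartile (adjusted p = 0.969), so its call depended on these settings.

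The glucocorticoid response element (GRE) was in 33 of 490 clusters of the MCF10A-named parental list, 6.73% against 0.408% of flanks, and in 34 of 651 of the MCFDCIS-named one, 5.22% against 0.23% (Fisher's exact test, adjusted p = 1.55e-11 and 1.35e-12). It was in 6 of 99 MCFDCIS-named D4 clusters against 0 of 198 flanks (Fisher's exact test, adjusted p = 0.0054) and in 2 of 138 MCF10A-named D4 clusters (1.45%, adjusted p = 0.608). The TEAD consensus was at 60.6% against 50.5% and 59.6% against 51.3% in the parental lists (Fisher's exact test, adjusted p = 0.0015 and 0.00269), and RUNX at 7.55% against 3.27% and 8.14% against 3.84% (adjusted p = 0.00269 and 0.000676). The p53 consensus passed only in the MCF10A-named parental list, at 7.35% against 2.76% (Fisher's exact test, adjusted p = 0.000676). The RUNX calls in both parental lists (adjusted p = 0.0752 and 0.566, exact test) and the p53 call (0.274) were lost when whole clusters were searched, and the p53 call also with the central 200 bp (0.0577). The estrogen response element was in 0 clusters and 0 flanks of every list, so its absence from clusters carries no information.

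**Figure D2:**
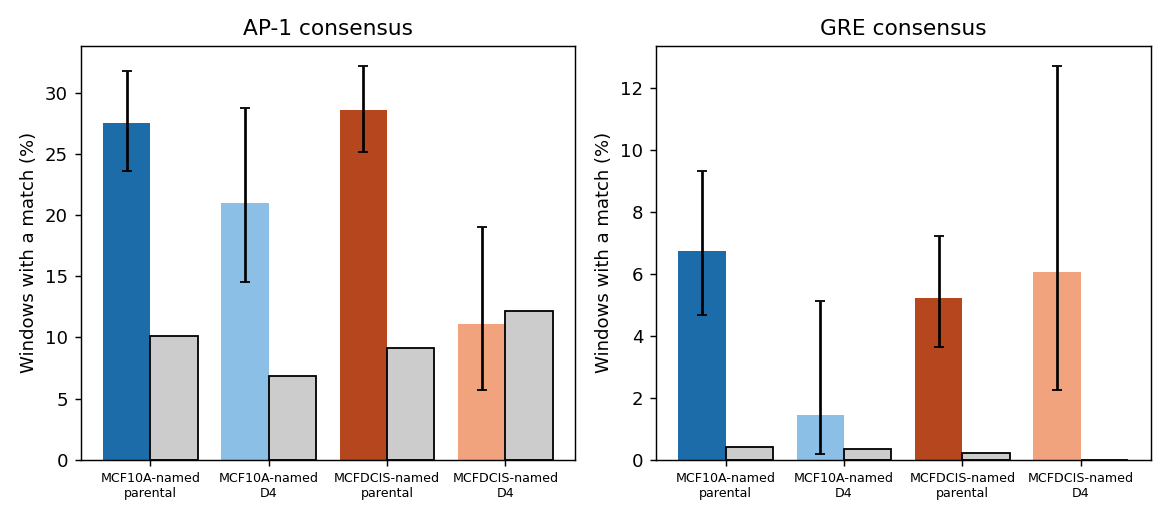
Share of central 500 bp windows with an AP-1 consensus (left) or a glucocorticoid response element (right) in the 4 lists, in percent, with exact 95% intervals, beside the share of flanking windows in grey. AP-1 stands above the flanks in 3 lists and at 11.1% against 12.1% in the MCFDCIS-named D4 list.

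Clusters lay at promoters more often than by placement in every list, and most of all in the MCFDCIS-named D4 list. There 34 of 99 clusters, 34.3% (exact 95% interval 25.1 to 44.6), were at promoters, against 12.6% (10.1 to 15.4) of the parental clusters, a difference of 21.7 points (Fisher's exact test, p = 3.62e-07). The 65 shared clusters, 23 of them at promoters, counted in both lists, so the sets were not independent. In the MCF10A-named lists the shares were 9.42% (5.11 to 15.6) in D4 and 10.8% (8.21 to 13.9) in parental cells, a difference of -1.40 points (exact test, p = 0.754). Placement gave 3.77% to 4.37% (one-sided, p = 0.0001 in 3 lists, the smallest possible, and 0.0055 in the MCF10A-named D4 list, n = 138). The latter was lost with clusters above the median score (n = 69, p = 0.0848). Introns held 28.3% to 41.3% and intergenic sequence 34.3% to 53.7% of the clusters of a list.

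**Figure D3:**
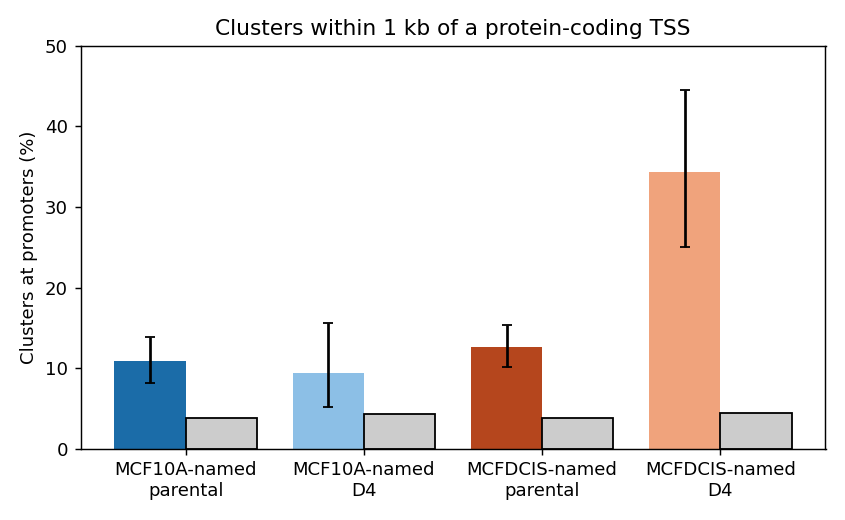
Share of clusters within 1 kb of a protein-coding transcription start site, in percent, in each of the 4 lists with exact 95% intervals, beside the mean of random placements in grey. The MCFDCIS-named D4 list stands at 34.3% and the others between 9.42% and 12.6%.

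Median cluster width did not separate D4 from parental lists, but it is a coarse measure. All clusters started on a 50 bp grid and the smallest width was 10 bp, so 60 and 110 bp are adjacent steps. Clusters of 10 bp made up 26.3% of the MCF10A-named parental and 37.7% of its D4 list, and 28.9% and 35.4% of the MCFDCIS-named ones. Clusters over 500 bp made up 21.6% and 28.3%, and 19.4% and 25.3%, in the same order. These shares were not tested. The median was 110 bp in parental and 60 bp in D4 cells in the MCF10A-named pair (permutation test, p = 0.846) and 60 bp in both MCFDCIS-named lists (p = 1). Among clusters of at most 500 bp, a limit chosen after the data were seen, the MCF10A-named difference of -50 bp passed the threshold (permutation test, p = 0.002). The median GC content of the central 500 bp was 47.8% in the MCF10A-named parental list and 42.1% in its D4 list, a D4 minus parental difference of -5.70 points (permutation test, p = 2e-05). The MCFDCIS-named medians were 47.0% and 48.4%, a difference of 1.40 points (permutation test, p = 0.275). Placement gave 40.8% to 41.4%, and the lists exceeded it (p = 0.001, the smallest possible) except the MCF10A-named D4 list (n = 138, p = 0.137).

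Clusters were unevenly spread over the chromosomes in every list (chi-square statistics of 448.2, 194.0, 538.2 and 139.3, Monte Carlo p = 0.0001 for each, the smallest possible). They crowded into 3 regions. The stretch from 127 to 130 Mb of chromosome 8, which holds MYC, had 67 clusters in the MCF10A-named parental list, 21 in its D4 list, 61 in the MCFDCIS-named parental list and 5 in its D4 list. In the same order, 73 to 75 Mb of chromosome 10 had 45, 17, 41 and 7 clusters, and 17 to 19 Mb of chromosome 17, which holds SREBF1 and RAI1, had 32, 12, 31 and 8. The uneven spread was not confined to these regions. In the MCFDCIS-named parental list 19q held 152.9 clusters per 100 Mb against 24.6 on 19p, and 5q 60.1 against 12.9 on 5p. The largest excess in the MCFDCIS-named D4 list was on chromosome 19, with 13 clusters against 2.04 expected from its length. The distribution over chromosomes did not differ detectably between D4 and parental lists (permutation test, p = 0.888 in the MCF10A-named and 0.753 in the MCFDCIS-named pair). This test counted the 67 and 65 shared clusters in both lists of a pair, which lessens any difference.

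**Figure D4:**
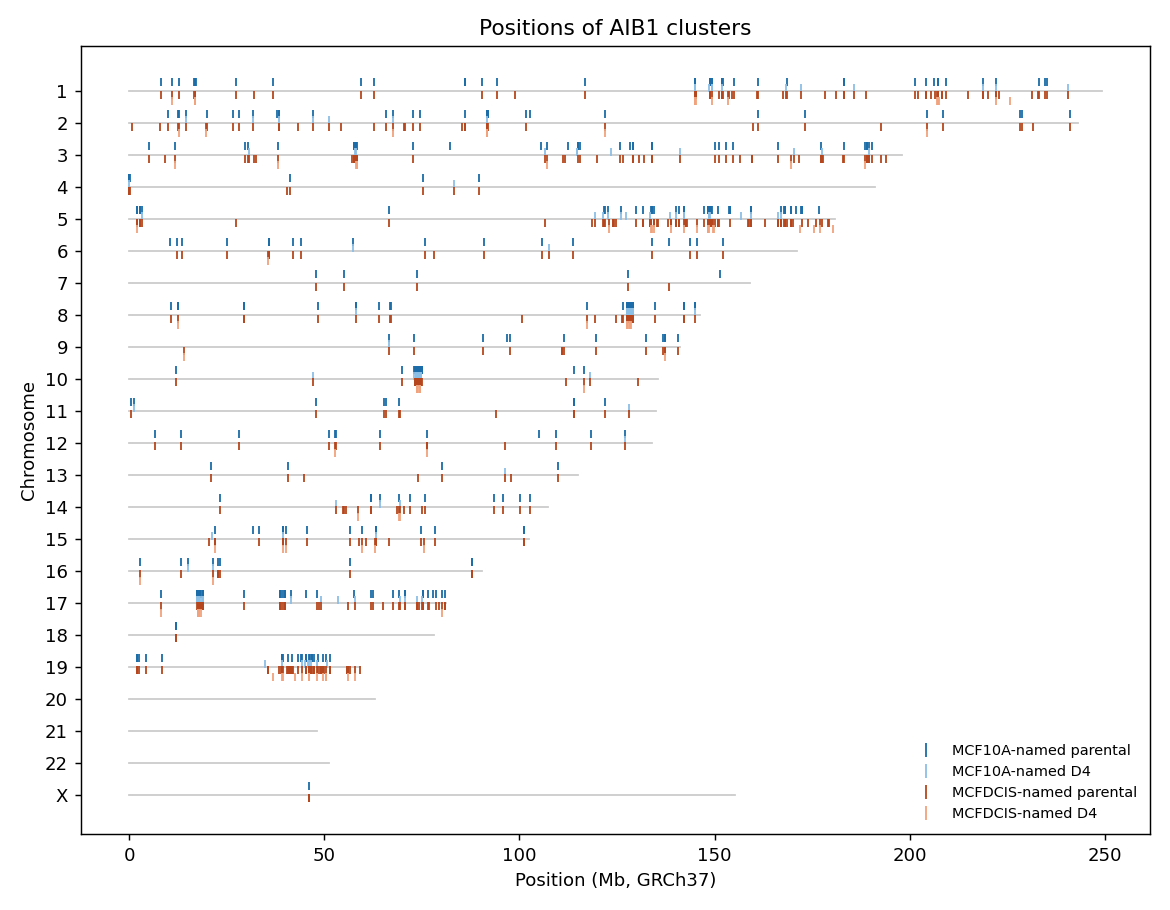
Positions of the clusters of the 4 lists (colours, 1 tick per cluster) along chromosomes 1 to 22 and X, in Mb on GRCh37. Ticks crowd at 127 to 130 Mb of chromosome 8, 73 to 75 Mb of chromosome 10 and 17 to 19 Mb of chromosome 17. None lie on chromosomes 20, 21 and 22, and it is not known whether the authors' run covered these.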

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

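Of the tests here, those of the weaker copy, of the MCFDCIS-named clusters found only in D4, of the MCF10A-named ones in neither parental list, of extra DNA copies, of broad or dense-region clusters, of stronger against weaker clusters within a list and of promoters among D4-only clusters were chosen after related results had been seen, and those of the MCF10A-named D4-only clusters, of near-identical copies and of the score-limited parental clusters rest on sets of clusters chosen after the data were seen. The D4 minus parental promoter share differed between the line names by 23.1 points (permutation test, p = 6e-05, adjusted p = 0.00084 over 14 tests), with -1.40 points in the MCF10A-named and 21.7 points in the MCFDCIS-named pair. The parental lists share 307 clusters, so the permuted sets were not independent.

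The first pattern is the smaller number of clusters in the D4 lists: outside the dense regions, 39.8% (29.5 to 50.8) of MCF10A-named D4 clusters lay within 1 kb of a cluster of their own-named parental list, and 72.2% (60.9 to 81.7) of MCFDCIS-named ones. The 53 MCF10A-named D4 clusters absent from that list held AP-1 in 34.0% against 8.49% of flanks (Fisher's exact test, p = 0.000197), which argues against random positions as their whole source. Input signal at these clusters was not examined, so input fluctuations are not excluded. A weaker copy of that list is not excluded either, since real sites can miss the cutoff of a single parental list. Of these 53, 30 were in the MCFDCIS-named parental list, so a weaker readout of sites from both parental lists stays open. For the 23 in neither list (AP-1 26.1%, 10.2 to 48.4, exact test, p = 0.161) chance cannot be told apart from binding because they are too few. For the MCFDCIS-named list, whose threshold is not given in the sources used here, a weaker copy cannot be told apart from a different set, nor can chance or input fluctuations from binding in its 22 unmatched clusters, because AP-1 was at 4.55% against 9.09% of flanks there (exact test, p = 0.658) but not enriched in its 57 matched clusters either (15.8% against 14.9%, p = 1), and 36.4% of the 22 lay at promoters against 5.03% by placement (p = 0.0001, the smallest possible). Lower depth or weaker enrichment of the D4 libraries, and a difference in AIB1 between D4 and parental cells, both stay open and untested.

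The second pattern is the crowding of clusters into parts of chromosomes 8, 10 and 17. Of the 260 different clusters there, 0.769% (0.0933 to 2.75) had another close match in the genome, which argues against reads shared between near-identical copies. AP-1 was enriched over flanks with an odds ratio of 2.31 inside these regions (Fisher's exact test, p = 0.000584) and 3.76 outside, and the difference passed the threshold narrowly (permutation p = 0.0433). The lower ratio is what extra DNA copies would give, and the enrichment that remained is what they would not give alone. Clusters in these regions were also wider. Without them the MCF10A-named parental list fell from 490 clusters and 348.4 kb to 346 clusters and 134.7 kb. Only the central 500 bp was searched and width was not matched, so the lower ratio cannot decide on extra copies. No biological explanation was tested.

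The third pattern is the lower AP-1 share in the MCFDCIS-named D4 list. Without the dense regions and clusters over 500 bp the difference was -18.2 points (Fisher's exact test, p = 0.00259), which argues against more broad or dense-region clusters as its cause. Parental clusters no stronger than the D4 upper quartile held AP-1 in 17.7%, inside the D4 interval of 5.68 to 19.0, so weaker clusters carrying the motif less often may account for the difference, provided the score has the same scale in both lists. Within the parental list alone, the clusters above the median score held AP-1 in 35.3% and those below in 21.8% (exact test, adjusted p = 0.000732 over 8 tests). A difference between D4 and parental AIB1 stays open.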

How the results depend on the processing

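The alternatives without the dense regions, up to 500 bp, without second matches, without promoter clusters, against the union and against score-limited parental clusters were added after seeing the data. No paired analysis was possible because the lists carry no replicate values, and leaving out replicates could not be run for the same reason. The filter on lower-case sequence was not run, and exchanging the cell lines only swaps names. Over 68 results, 364 of 419 alternative values kept their direction and side of the threshold, or for counts stayed close to the original. Some of these could not change. All clusters lay on chromosomes 1 to 22 and X, overlapping clusters had identical ends, and filtering both lists of a pair at their medians all but fixes their ratio. The count of 364 is therefore not a measure of robustness. The cause was not tested unless given.

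Keeping clusters above the median score, with ties at the median taken in file order, left 245, 69, 326 and 50 clusters by construction. The MCF10A-named D4 list without the dense regions held 88. With draws from the union of the lists, the shares of 48.6% and 65.7% (D4 in parental) and 62.7% and 6.52% (between line names) lay below the expected number, which this union raises by construction. For the first 2 shares this was not beyond chance (exact hypergeometric test, one-sided, p = 0.0716 and 0.0667), but for those between line names it was (p = 8.55e-14 and 0.0396). Because the expected number is raised, these p-values do not show avoidance between lists. The MCF10A-named promoter difference turned to 2.58 points with 5 kb, 2.51 points with the TSS of every gene and 0.939 points without the dense regions, none past the threshold. The MCF10A-named width difference was 314.5 bp in means (permutation test, p = 0.0638) and -50 bp up to 500 bp (p = 0.002). Gene lists past the threshold numbered 2 in the MCF10A-named parental, 1 in the MCF10A-named D4 and 0 in the MCFDCIS-named D4 list with 25 kb. They numbered 1 and 2 in these D4 lists with the nearest gene only, and 0 in the MCFDCIS-named D4 list above the median score. Matrix genes near MCF10A-named parental clusters fell to 0 with 25 kb. Motifs past the threshold numbered 3 and 2 in the MCF10A-named parental and D4 lists when whole clusters were searched. AP-1 in the MCFDCIS-named D4 list rose above its flanks at 13.1% with whole clusters, 11.1% with flanks 20 kb away and 13.5% up to 500 bp, none past the threshold. The AP-1 difference was 2.26 points (whole clusters) and 1.28 points (score-limited parental clusters) in the MCF10A-named pair, and -5.61 and -6.58 points, no longer past the threshold, in the MCFDCIS-named pair. The MCFDCIS-named promoter difference kept its call under all alternatives run. Unknown depth limits all counts of clusters.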

Other observations

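The tests here were chosen after the data were seen. D4-only and parental-only are meant within a pair of the same line name. In the MCF10A-named pair AP-1 was in 29.8% of 423 parental-only clusters, 13.4% of 67 shared clusters and 28.2% of 71 D4-only clusters. In the MCFDCIS-named pair it was in 30% of 586 parental-only, 15.4% of 65 shared and 2.94% of 34 D4-only clusters. Promoters held 35.4% of the MCFDCIS-named shared clusters and 32.4% of its D4-only clusters, against 10.1% of the parental-only ones. In the MCF10A-named pair the promoter shares were 14.9%, 4.23% and 10.2% in the same order. Outside the dense regions, 30 of the 53 MCF10A-named D4-only clusters were in the MCFDCIS-named parental list, and 23 were in neither parental list. The differences between these classes were not tested.

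Within the MCFDCIS-named parental list promoters held 7.67% of the clusters above the median score and 17.5% of those below (Fisher's exact test, adjusted p = 0.000732 over 8 tests). Against parental clusters no stronger than the D4 upper quartile, of which 19.2% lay at promoters, the D4 promoter share of 34.3% was still higher by 15.1 points (exact test, p = 0.0143), if the score has the same scale in both lists.

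No cluster of any list lay on 18q or Xq.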
